A study of Rattus norvegicus with 12 samples.

How the data were processed

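Total RNA from the right lobe of the liver of Sprague-Dawley rats was labelled with biotin and hybridised to Affymetrix Rat Genome 230 2.0 arrays, 1 array per sample. The 12 samples fall into 4 groups of 3: normal liver at 0h and liver after 2, 4 and 6 weeks of feeding with a high-fat emulsion, a diet given to produce a nonalcoholic fatty liver. Per the labels, all animals were 12 weeks old and the 3 samples of a group are technical replicates. How many rats stand behind a group is not given in the sources used here.

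The deposited values are probe set signal intensities on a linear scale, 1 column per array. GCOS 2.0 is named as the software in the submitters' processing notes. From the values, each array had been scaled to a common mean: the mean signal after trimming 2% at each end lay between 500.2 and 500.3 on every array. A deposited sheet repeats the signal intensities to 1 decimal, with no value differing by more than 0.1 over the 31099 probe sets. The same sheet holds, per the file headers, log2 ratios and the matching linear ratios of each fed array against each 0h array, 9 pairs per fed group, made by the authors. No detection calls were used here, so the filter on dim probe sets rested on the signals.

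Signals were converted to log2(signal + 1), so that fold changes are on that scale. The added 1 shrinks the changes of dim genes, but background counted as signal can also distort them. After leaving out 57 array controls, 31042 probe sets remained. Gene symbols came from the platform table and were brought up to date by symbol, older symbol or accession through the RefSeq gene table of assembly GRCr8, which was used for names only. A single symbol was assigned to 19875 probe sets (12357 through a current symbol, 2983 through an older one, 3053 through an accession and 1482 kept as in the platform table). No symbol was found for 11121, several for 23, and for another 23 the symbol and the accession named different genes. Each of the 13892 symbols was represented by the probe set with the highest mean log2 signal over the 12 arrays, and where another probe set of a named gene moved the opposite way this is said beside the gene. Genes whose mean log2 signal exceeded the 30th percentile of all probe sets (5.45) were tested, 11328 in all.

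Precision was limited by the number of arrays. The median within-group SD was 0.16 on the log2 scale, and 0.11 for genes with a mean above 8. Correlations across genes were 0.973 to 0.980 within groups and 0.953 to 0.972 between groups.

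A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom), and 5 comparisons were read from it: each fed group against 0h, 4 against 2 weeks and 6 against 4 weeks. A moderated F test covered the 3 fed groups against 0h. All p-values were adjusted with Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. Gene lists for metabolic pathways, stress responses, liver cell types and signs of other tissue, sampling time or animal differences were written before the data were examined, 34 in all. Those with at least 5 measured genes, 33 lists, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. For each list the number of called members is given over all genes and adjusted over the list alone.

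A gene was treated as dim in a group when its signal lay under the 30th percentile of the array (a signal of 45.5 to 54.0) on all 3 arrays. The fold of such a gene is given as a lower bound, from the mean of the brighter group over the mean, in the dim group, of the percentile or the gene's own signal, whichever was higher. The same bound was taken, a choice made after the data were seen, for named genes with 1 or 2 arrays under the percentile.

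Named genes were chosen by a rule fixed before the data were examined. For each fed group against 0h it takes the 8 highest and 8 lowest log2 changes among called genes with a characterised symbol whose arrays do not overlap between groups, and 4 of each for the stepwise comparisons. It adds a fixed list of benchmark genes of lipid metabolism, inflammation and fibrosis, and for each list past camera the 4 called members with the largest change. Some genes that meet the rule are not reported here; they stayed in all tests and counts.

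The procedure was tested on simulated data made from the measured means and spreads of the genes. Of the same 11328 genes, 200 were changed in the simulated comparison of 6 weeks with 0h. The procedure recovered 22 of 54 genes changed 1.5-fold, 56 of 77 changed 2-fold and 61 of 69 changed 4-fold. Of its 145 calls, 6 were false, and a list shifted by -0.5 was called with 0 other lists. Means and spreads alone do not carry the correlation between genes, so the simulation cannot test list calls where genes vary together. In the measured data 40 list calls were lost with an estimated correlation.

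The 3 comparisons against 0h share their control arrays. Their agreement was therefore set beside 20 simulations of unchanged groups that share simulated controls with the measured spread, and beside the overlap of independent lists of the same lengths.

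Alternatives fixed before the data were examined were quantile normalization, median centring, a pseudocount of 16, no filter, a filter at the 50th percentile, eBayes with trend and robust, the replicate number as a block, the mean of a gene's probe sets, all probe sets tested separately, the rounded signals, a fit of only the 2 groups compared, thresholds of 2-fold and of 1.5-fold (limma treat), unadjusted p-values, and leaving out each array in turn. Chosen after the data were seen were the authors' deposited log2 ratios, a fit of the fed groups alone, and counts without the genes of 4 control lists. Tables were read with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3) and figures drawn with matplotlib 3.10.9. Probe sets without a symbol were left out of the gene tests and tested apart. Array scanner files were not analysed here.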

Results

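Expression was measured in 12 liver samples, 3 each from untreated rats at 0h and from rats fed a high-fat emulsion for 2, 4 or 6 weeks. Each sample was hybridised to 1 array with 31099 probe sets. After the authors' scaling the median signal per array lay between 118 and 130 and the highest between 48817 and 60210. The 3 arrays of a group differed by a median SD of 0.16 on the log2 scale. The 0h group was the only unfed group, so feeding, elapsed time and any other property of those 3 samples were compared together. The 3′ to 5′ log2 signal ratio of GAPDH, a sign of RNA integrity, was 0.16 ± 0.08 (SD, n = 3) at 0h, 0.47 ± 0.03 at 2 weeks, 0.33 ± 0.03 at 4 weeks and 0.33 ± 0.04 at 6 weeks. That of actin was 1.23 ± 0.18, 1.42 ± 0.12, 1.18 ± 0.22 and 1.44 ± 0.07.

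The comparison of 2 weeks with 0h addressed how liver transcription differed early in the development of the fatty liver model. Cholesterol synthesis was lower after 2 weeks. Tm7sf2, a sterol reductase, fell 4.17-fold (log2 change -2.06 ± 0.06 SE, n = 3 arrays per group, adjusted p = 4.01e-08), and Idi1, which isomerises isoprenoid precursors, fell 2.10-fold (-1.07 ± 0.06). Sqle, which makes squalene epoxide, fell 1.51-fold (-0.60 ± 0.12). Of the 25 measured genes of this list, 19 fell, 3 rose and 3 were not called, with the same counts adjusted over the list alone (camera, adjusted p = 4.27e-08). Of the enzymes of bile acid synthesis, Cyp7a1, which starts the classic pathway, fell by 0.50 ± 0.08 on the log2 scale, and Cyp8b1, the sterol 12-hydroxylase, 2.72-fold (-1.44 ± 0.05). The bile acid list did not pass, with 8 of 26 genes higher and 8 lower, or 9 and 9 adjusted over the list alone (median 0.13, mean 0.01, test direction down; camera, adjusted p = 0.998).

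Single genes of fatty acid synthesis moved both ways, and their list did not pass. At 2 weeks Scd, which desaturates fatty acids, rose 1.39-fold (0.47 ± 0.09, adjusted p = 0.0038), and the NADPH-producing malic enzyme Me1 rose 1.84-fold (0.88 ± 0.05). Fasn (0.14 ± 0.09, adjusted p = 0.275) and the lipogenic regulator Srebf1 (0.15 ± 0.05, adjusted p = 0.058) did not pass. With the mean of their probe sets both passed (Fasn 0.32, adjusted p = 0.0105; Srebf1 0.34, adjusted p = 0.000812), and Srebf1 also passed with the filter at the 50th percentile (adjusted p = 0.0483) and with trend and robust (0.0242). Of 19 fatty acid synthesis genes 5 rose and 7 fell, or 6 and 8 adjusted over the list alone (camera, adjusted p = 0.781), and of 23 lipid droplet genes 6 rose and 7 fell, also adjusted over the list alone (median 0.02, mean 0.08, test direction down; camera, adjusted p = 0.937). Among 30 fatty acid oxidation genes 19 rose, 3 fell and 8 were not called, the same adjusted over the list alone (camera, adjusted p = 0.000139). This list lost its call with adjusted p = 0.142 with an estimated correlation. Its risers included Vnn1, a pantetheinase of coenzyme A turnover (1.62 ± 0.07), and the fatty acid hydroxylase Cyp4a8 (1.89 ± 0.21), while Cpt1a, which admits long-chain fatty acids to mitochondria, fell 2.55-fold (-1.35 ± 0.06). Pdk4, a brake on glucose oxidation, fell 2.21-fold (-1.14 ± 0.09). In amino acid breakdown and the urea cycle, 7 of 26 genes fell and 4 rose, or 10 and 4 adjusted over the list alone (camera, adjusted p = 0.0123; adjusted p = 0.4 with an estimated correlation). Sds, which deaminates serine, fell 8.80-fold (-3.14 ± 0.10), and the aspartate aminotransferase Got1 fell 2.46-fold (-1.30 ± 0.06).

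Heat shock, connective tissue and proliferation genes rose at 2 weeks. Of 15 heat shock genes 11 rose and none fell by the test over all genes, against 12 and 1 adjusted over the list alone (camera, adjusted p = 4.91e-06). The small chaperone Hspb1 rose 3.64-fold (1.86 ± 0.13), and the co-chaperone Stip1 1.69-fold (0.76 ± 0.10). Of 30 genes of stellate cells and matrix, 19 rose, 1 fell and 10 were not called, the same adjusted over the list alone (camera, adjusted p = 1.18e-06). The collagen chain Col1a1 rose 2.11-fold (1.08 ± 0.17) and the matrix proteoglycan Lum 2.20-fold (1.14 ± 0.16), whereas Lox, which crosslinks collagen, fell 7.16-fold (-2.84 ± 0.14). Tgfb1, the fibrogenic cytokine, was dim at 0h and at least 4.43-fold higher at 2 weeks. In the cell cycle list 10 of 31 genes rose and 1 fell, or 12 and 1 adjusted over the list alone (camera, adjusted p = 0.00168; adjusted p = 0.0733 with an estimated correlation), led by Rrm2, a subunit of ribonucleotide reductase (1.60 ± 0.07), and the mitotic kinase Cdk1 (1.44 ± 0.16).

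Markers of other cell types moved in both directions at 2 weeks. Macrophage markers rose in 9 of 21 cases with none falling (10 and 1 adjusted over the list alone; camera, adjusted p = 0.00168; adjusted p = 0.0733 with an estimated correlation), among them the growth factor receptor Csf1r (0.61 ± 0.08) and the complement chain C1qc (0.64 ± 0.10). Endothelial markers rose in 5 of 18 cases, also adjusted over the list alone (camera, adjusted p = 0.0254; adjusted p = 0.102 with an estimated correlation), including the receptor kinase Tie1 (0.65 ± 0.09). Red cell and platelet genes rose in 4 of 8 cases, or 5 adjusted over the list alone (camera, adjusted p = 0.0123; adjusted p = 0.0733 with an estimated correlation), with Alas2, the erythroid heme enzyme, up 2.01-fold (1.01 ± 0.08). Lymphocyte markers fell in 3 of 20 cases, also adjusted over the list alone (camera, adjusted p = 0.00718; adjusted p = 0.0708 with an estimated correlation), among them the granzyme Gzma (-0.82 ± 0.11). Genes of the polymorphic major histocompatibility complex fell in 7 of 14 cases and rose in 2, or 8 and 2 adjusted over the list alone (camera, adjusted p = 0.0123; adjusted p = 0.142 with an estimated correlation). The class I gene RT1-A3 rose 4.51-fold (2.17 ± 0.05), but 1 of its 2 other probe sets moved the opposite way.

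In total, 1762 of 11328 genes were higher and 1423 lower at 2 weeks (limma, adjusted p under 0.05), 314 of them by at least 2-fold. The labels call the 3 replicates technical, so these p-values measure only the spread between arrays. Of 33 lists 14 passed camera, 3 of them also with an estimated correlation (cholesterol synthesis, stellate cells and matrix, heat shock). With quantile normalization 3 further lists lost their calls: proteasome genes (9 of 28 higher, also adjusted over the list alone; adjusted p = 0.0129 before and 0.0847 after), oxidative phosphorylation (14 of 40 higher and 3 lower, 15 and 3 adjusted over the list alone; 0.0194 and 0.186) and drug-metabolising enzymes (14 of 28 higher and 4 lower, also adjusted over the list alone; 0.0226 and 0.0817). These were not called with an estimated correlation either (adjusted p = 0.142, 0.4 and 0.521). The last also lost it without 0h replicate 3 (adjusted p = 0.0594), and its mean change (-0.01) had the opposite sign to its median (0.18).

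The largest falls at all 3 feeding times were in transcripts that set the 0h arrays apart. Cyp2c12, a steroid hydroxylase of female rat liver, had a mean signal of 33924 at 0h and 459 at 2 weeks, 73.8-fold less (-6.21 ± 0.11, adjusted p = 2.18e-09). A1bg, a plasma protein whose transcript is also female-biased in rat liver, fell 176-fold (-7.46 ± 0.22) at 2 weeks, 289-fold at 4 and 180-fold at 6. The male-specific hydroxylase Cyp2c11 was abundant at 0h too, with a signal of 20718, and rose by 0.57, 0.78 and 0.63 on the log2 scale. Of 17 sex-biased transcripts, 7 rose and 9 fell at 2 weeks, 8 and 9 at 4 weeks and 6 and 9 at 6 weeks, the same adjusted over the list alone. This list holds male-biased and female-biased genes, which can move opposite ways, so camera, which tests a single direction, can miss its shift. Its camera test missed the threshold (adjusted p = 0.0656, 0.207 and 0.053). It passed with quantile normalization (0.0463, 0.0474 and 0.0402) and with median centring (0.0244, 0.0449 and 0.0147). At 2 weeks it also passed without 0h replicate 3 (adjusted p = 0.0395), and at 6 weeks with no filter (0.0359) or without 0h replicate 1 (0.0382), 0h replicate 3 (0.0369), 6-week replicate 1 (0.0372) or 6-week replicate 2 (0.0429).

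The pancreatic digestive enzyme Cpa1 had a signal of 6261 at 0h and fell at least 111-fold at 2 weeks, 126-fold at 4 weeks and 112-fold at 6 weeks, lower bounds since 2, 3 and 2 arrays of these groups lay under the background level. Clock genes differed as well. Nr1d1, a repressor of the circadian clock, fell 11.7-fold at 2 weeks (-3.55 ± 0.21, adjusted p = 3.43e-06) and at least 13.3-fold and 12.8-fold at 4 and 6 weeks, with 2 arrays and 1 array under the background level, and Bmal1, its target, rose by 0.79, 0.79 and 0.80. The clock gene Per2 rose 5.88-fold at 2 weeks (2.56 ± 0.10). The clock list as a whole, with 6 of 16 genes higher and 4 lower at 2 weeks, also adjusted over the list alone, did not pass camera (adjusted p = 0.119). It too holds genes that can move opposite ways, which a test for a single direction can miss.

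**Figure D1:**
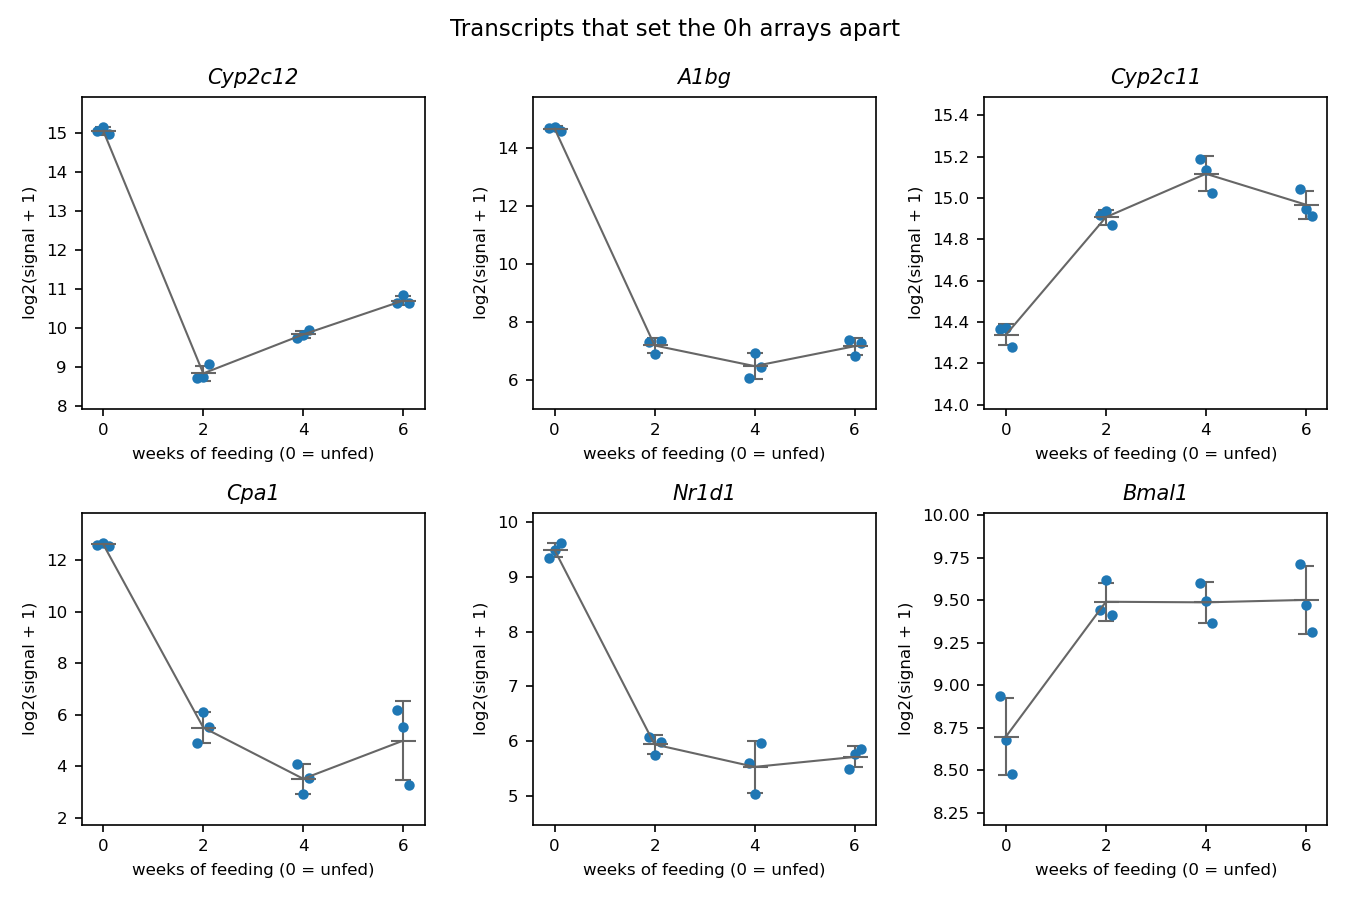
Log2(signal + 1) of 6 transcripts against weeks of feeding (0 = unfed); points are arrays, lines join group means and bars are the SD of 3 arrays. Cyp2c12, A1bg, Cpa1 and Nr1d1 were highest on the 0h arrays, where Cyp2c11 and Bmal1 were lowest.

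At 4 weeks, compared with 0h to follow the fatty liver model at its middle time point, the fall of sterol genes was larger. Sqle fell 7.76-fold (-2.96 ± 0.12, adjusted p = 1.76e-07, n = 3 arrays per group), Tm7sf2 6.84-fold (-2.77 ± 0.06) and Idi1 5.28-fold (-2.40 ± 0.06). Of 25 cholesterol synthesis genes 23 fell and none rose, also adjusted over the list alone (camera, adjusted p = 4.98e-21). Cyp7a1 fell 6.74-fold (-2.75 ± 0.08) and Cyp8b1 2.32-fold (-1.21 ± 0.05). Scd rose 1.92-fold (0.94 ± 0.09) and Me1 2.23-fold (1.16 ± 0.05), while Fasn fell 1.39-fold (-0.48 ± 0.09). Igfbp1, an insulin-repressed binding protein of growth factors, fell 1.96-fold (-0.97 ± 0.06).

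The lists of oxidative phosphorylation, fatty acid oxidation, proteasome and heat shock genes rose at 4 weeks. In oxidative phosphorylation 25 of 40 genes rose and 1 fell, or 26 and 1 adjusted over the list alone (camera, adjusted p = 1.07e-08; adjusted p = 0.0729 with an estimated correlation), with small changes such as 0.56 ± 0.07 for the complex I subunit Ndufv2 and 0.49 ± 0.05 for cytochrome c, Cycs. In fatty acid oxidation 20 of 30 rose and 2 fell, or 20 and 3 adjusted over the list alone (camera, adjusted p = 2.18e-07; adjusted p = 0.0729 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase that responds to fatty acids, rose 2.61-fold (1.38 ± 0.07) and the thiolase Acaa2 1.90-fold (0.93 ± 0.07), and Cpt1a fell 2.09-fold (-1.07 ± 0.06). Proteasome genes rose in 15 of 28 cases, or 17 adjusted over the list alone, and none fell (camera, adjusted p = 5.05e-05; adjusted p = 0.0502 with an estimated correlation), with the regulatory subunit Psmd1 up by 0.88 ± 0.08. Heat shock genes rose in 10 of 15 cases (10 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.000155), including Hspb1 (0.71 ± 0.13) and the mitochondrial chaperonin Hspe1 (0.55 ± 0.05).

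Macrophage and neutrophil markers and cytokine genes were lower at 4 weeks than at 0h. Macrophage markers fell in 13 of 21 cases and rose in 1, also adjusted over the list alone (camera, adjusted p = 2.12e-05), among them the haemoglobin scavenger receptor Cd163 (-0.77 ± 0.11) and Lgals3, a galectin of activated macrophages (-0.58 ± 0.06). Neutrophil markers fell in 4 of 8 cases, also adjusted over the list alone (camera, adjusted p = 0.0166; adjusted p = 0.073 with an estimated correlation). The calcium-binding proteins S100a8 and S100a9 fell 2.31-fold (-1.21 ± 0.10) and 1.80-fold (-0.85 ± 0.06). Cytokine genes fell in 8 of 22 cases and rose in 2, also adjusted over the list alone (camera, adjusted p = 0.0136; adjusted p = 0.0729 with an estimated correlation). The neutrophil chemokine Cxcl1 fell 1.98-fold (-0.98 ± 0.09) and the lymphocyte chemokine Ccl5 1.78-fold (-0.83 ± 0.10), whereas Cxcl9, induced by interferon gamma, rose 1.64-fold (0.71 ± 0.14).

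In total, 1621 genes were higher and 1714 lower at 4 weeks (48.6% higher), 380 of the changes being at least 2-fold. With median centring the split was 1906 higher and 1122 lower (62.9% higher). Of 33 lists 11 passed camera, 3 of them also with an estimated correlation (cholesterol synthesis, macrophage markers, heat shock). The list of drug-metabolising enzymes (13 of 28 higher and 8 lower, 15 and 8 adjusted over the list alone, median 0.24 but mean -0.07; adjusted p = 0.03) lost its call with an estimated correlation (adjusted p = 0.621), quantile normalization (0.348), or without 0h replicate 1 (0.0532), 0h replicate 3 (0.0713) or 4-week replicate 1 (0.0547). The immediate early list, with Sgk1 down 2.45-fold (6 of 20 lower and 2 higher, also adjusted over the list alone; adjusted p = 0.0401), lost it with an estimated correlation (adjusted p = 0.0915) or without 0h replicate 3 (0.0708), 4-week replicate 2 (0.061) or 4-week replicate 3 (0.0796). Lymphocyte markers, with the pore-forming protein Prf1 down 2.39-fold (7 of 20 lower, 9 adjusted over the list alone; adjusted p = 0.0415), lost it with an estimated correlation (adjusted p = 0.0915), quantile normalization (0.0589) or no filter (0.062), or without 0h replicate 3 (0.111), 4-week replicate 3 (0.0796) or 6-week replicate 3 (0.0508).

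**Figure D2:**
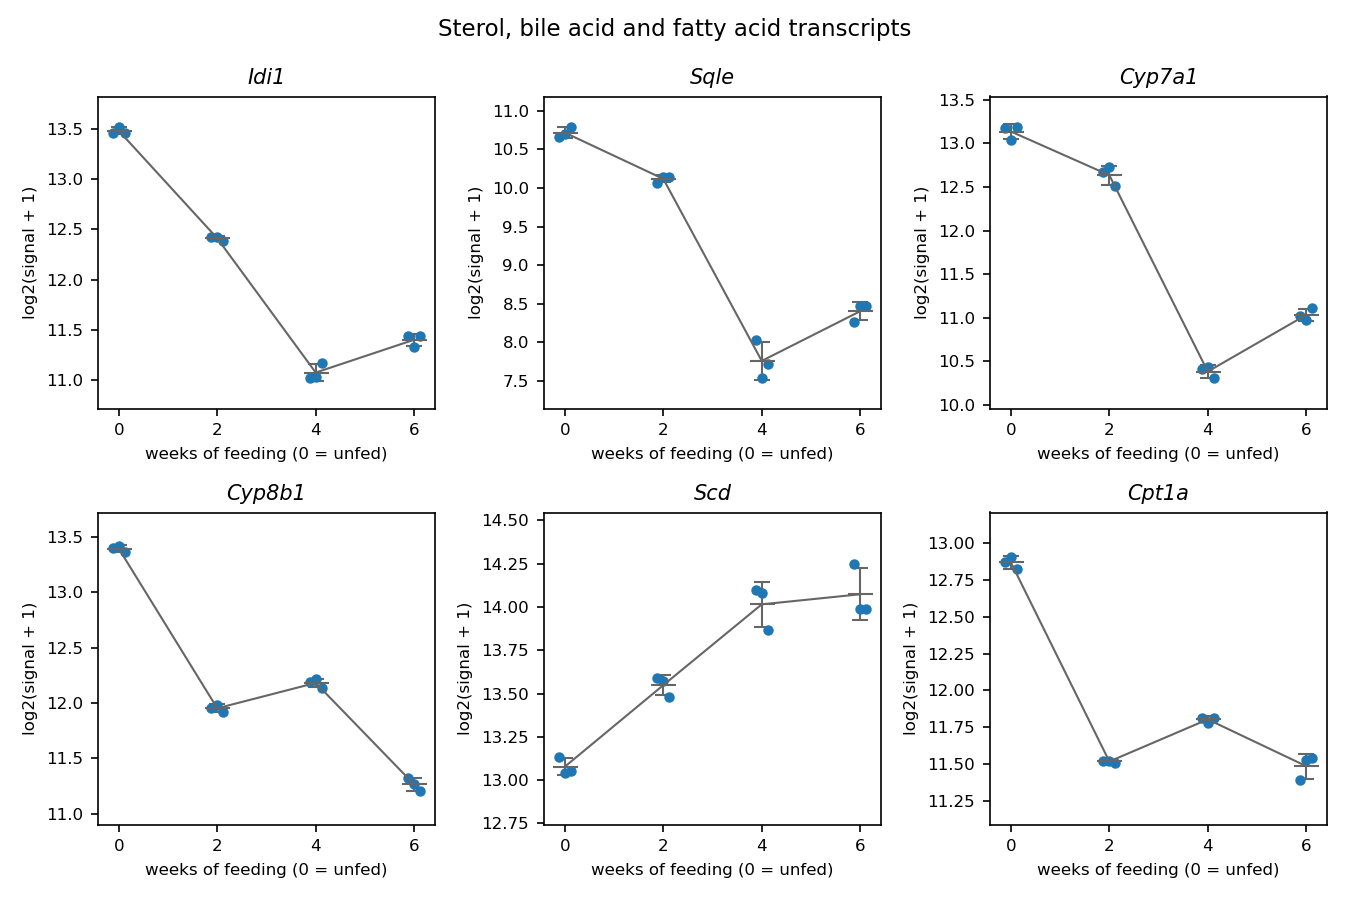
Log2(signal + 1) of 6 sterol, bile acid and fatty acid transcripts against weeks of feeding (0 = unfed); points are arrays, lines join group means and bars are the SD of 3 arrays. Idi1, Sqle and Cyp7a1 were lowest at 4 weeks and Cyp8b1 at 6 weeks, while at all 3 feeding times Scd lay above and Cpt1a below its 0h arrays.

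At 6 weeks, the latest time point of the model, histocompatibility genes were higher than at 0h. The class II genes RT1-Bb and RT1-Da rose 4.07-fold (2.03 ± 0.06, adjusted p = 3.95e-08, n = 3 arrays per group) and 3.21-fold (1.68 ± 0.05). Of 14 histocompatibility genes 10 rose and none fell, or 11 and none adjusted over the list alone (camera, adjusted p = 2.06e-07). These genes are polymorphic, and their list was written as a sign of differences between animals. Whether such differences or feeding gave the rise was not tested. Cxcl9 rose 7.33-fold (2.87 ± 0.14). Cyp1a1, the hydroxylase induced through the aryl hydrocarbon receptor, rose at least 14.8-fold, as 2 arrays at 0h lay under the background level, and the methyltransferase Inmt 6.39-fold (2.68 ± 0.08).

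The sterol genes stayed below 0h at 6 weeks, 22 of 25 falling and none rising (23 adjusted over the list alone; camera, adjusted p = 1.91e-22). Tm7sf2 fell 7.13-fold (-2.83 ± 0.06) and Sqle 4.97-fold (-2.31 ± 0.12), and the bile acid enzymes Cyp7a1 and Cyp8b1 fell 4.30-fold (-2.10 ± 0.08) and 4.38-fold (-2.13 ± 0.05). Among genes of glucose handling, Igfbp1 fell 4.73-fold (-2.24 ± 0.06) and the gluconeogenic enzyme Pck1 1.40-fold (-0.49 ± 0.06). Amino acid and urea cycle genes fell in 12 of 26 cases and rose in 5, or 13 and 5 adjusted over the list alone (camera, adjusted p = 0.00203; adjusted p = 0.394 with an estimated correlation), with Sds down 5.36-fold (-2.42 ± 0.10). Fatty acid oxidation genes rose in 15 of 30 cases and fell in 4, or 19 and 4 adjusted over the list alone (camera, adjusted p = 0.00156; adjusted p = 0.302 with an estimated correlation), with Vnn1 up 3.74-fold (1.90 ± 0.07) and Cpt1a down 2.61-fold (-1.38 ± 0.06).

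Proteasome genes rose in 17 of 28 cases at 6 weeks and none fell, or 19 adjusted over the list alone (camera, adjusted p = 1.7e-05), among them the catalytic subunit Psmb6 (0.64 ± 0.07). Heat shock genes rose in 10 of 15 cases (11 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.00036), with Hspb1 up 2.77-fold (1.47 ± 0.13). Oxidative phosphorylation genes rose in 17 of 40 cases and fell in 1, or 18 and 1 adjusted over the list alone (camera, adjusted p = 0.000286; adjusted p = 0.302 with an estimated correlation), such as Ndufs3 (0.50 ± 0.07). Immediate early genes fell in 7 of 20 cases and rose in 2, or 7 and 3 adjusted over the list alone (camera, adjusted p = 0.0363; adjusted p = 0.15 with an estimated correlation). The growth-induced transcription factor Egr1 fell 4.24-fold (-2.08 ± 0.10) and the phosphatase Dusp1 2.93-fold (-1.55 ± 0.07).

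In total, 1658 genes were higher and 1427 lower at 6 weeks (53.7% higher), 325 of them by at least 2-fold. With median centring the split was 1710 and 1046 (62.0% higher). Of 33 lists 10 passed camera, 4 of them also with an estimated correlation (cholesterol synthesis, histocompatibility genes, proteasome, heat shock). The cell cycle list (7 of 31 higher and 1 lower, also adjusted over the list alone; adjusted p = 0.0427) lost its call with an estimated correlation (adjusted p = 0.302), no filter (0.0543), or without 0h replicate 2 (0.0941) or 6-week replicate 1 (0.0704). The complement and coagulation list (10 of 26 lower and 1 higher, also adjusted over the list alone; adjusted p = 0.0196) lost it with an estimated correlation (adjusted p = 0.527), median centring (0.0701), or without 0h replicate 2 (0.0509).

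**Figure D3:**
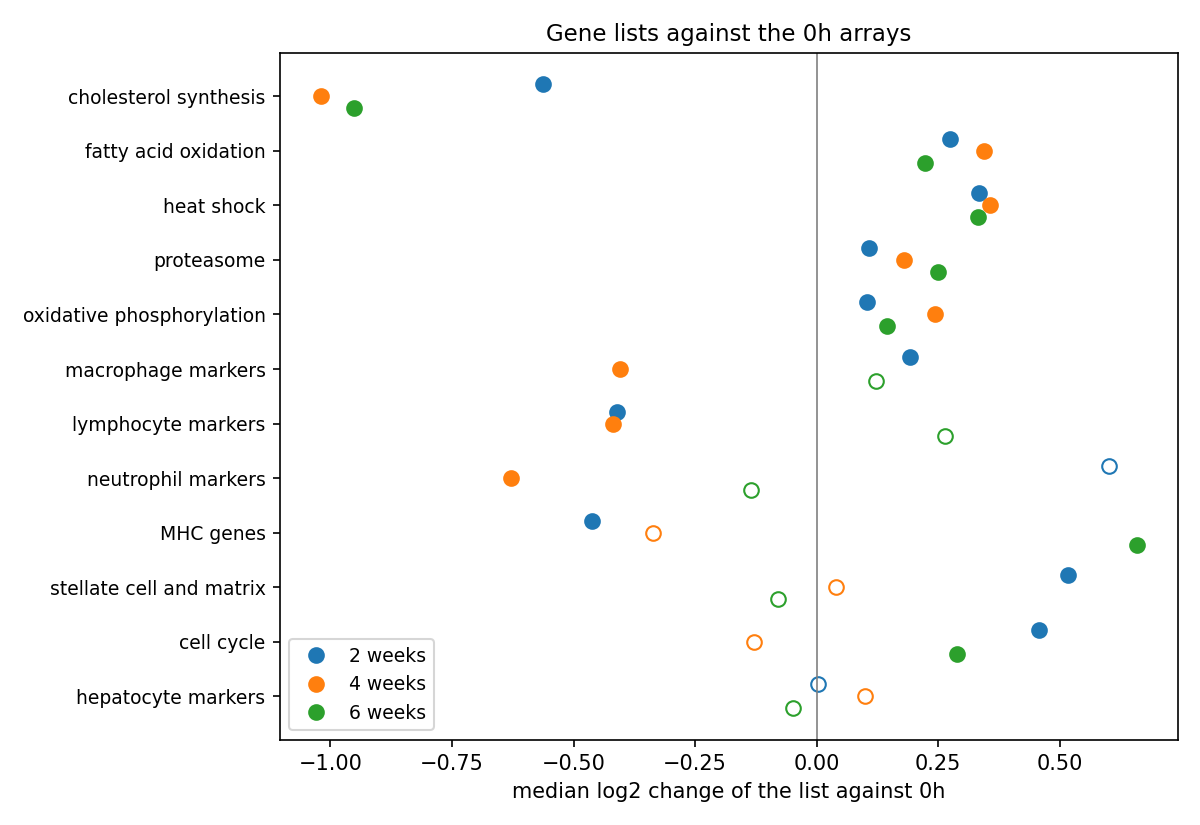
Median log2 change against 0h of 12 gene lists at 2, 4 and 6 weeks; filled circles passed camera at an adjusted p under 0.05. The cholesterol synthesis medians were -0.56, -1.02 and -0.95, and the lists of macrophage markers and histocompatibility genes changed sides between times.

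The step from 2 to 4 weeks was compared to show when in the model transcripts changed. Macrophage, neutrophil, matrix and cell cycle genes were lower at 4 than at 2 weeks. Macrophage markers fell in 18 of 21 cases and none rose (18 lower and 1 higher adjusted over the list alone; camera, adjusted p = 1.93e-14), with Cd163 down 1.98-fold (-0.98 ± 0.11, adjusted p = 0.000394, n = 3 arrays per group) and the lysosomal membrane protein Cd63 down 1.81-fold (-0.85 ± 0.06). S100a8 and S100a9 fell 3.97-fold (-1.99 ± 0.10) and 3.31-fold (-1.72 ± 0.06), and 4 of 8 neutrophil markers fell, 5 adjusted over the list alone (camera, adjusted p = 0.000198). The matrix list fell in 17 of 30 cases and rose in 1, or 18 and 1 adjusted over the list alone (camera, adjusted p = 1.2e-09). The collagen chain Col1a2 fell 1.91-fold (-0.93 ± 0.11), whereas Lox rose 23.1-fold (4.53 ± 0.14). Cell cycle genes fell in 13 of 31 cases, or 14 adjusted over the list alone (camera, adjusted p = 2.52e-08), with Rrm2 down 2.51-fold (-1.33 ± 0.07). Against 0h the matrix list, higher at 2 weeks, did not pass camera at 4 or 6 weeks (adjusted p = 0.819 and 0.511). At 4 weeks 3 of its 30 genes were higher and 3 lower, 1 and 3 adjusted over the list alone (median 0.04). At 6 weeks 5 were higher and 7 lower, 5 and 10 adjusted over the list alone (median -0.08 but mean 0.04).

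Endothelial markers fell from 2 to 4 weeks in 4 of 18 cases, 5 adjusted over the list alone (camera, adjusted p = 0.000711), including the hyaluronan receptor Lyve1 (-0.77 ± 0.06). Red cell and platelet genes fell in 5 of 8 cases, 6 adjusted over the list alone (camera, adjusted p = 0.000198), including the platelet chemokine Pf4 (-1.11 ± 0.09). Sterol synthesis fell further, in 20 of 25 cases with 1 rising, or 23 and 1 adjusted over the list alone (camera, adjusted p = 1.68e-20), with Sqle down 5.13-fold (-2.36 ± 0.12). Cyp7a1 fell 4.76-fold (-2.25 ± 0.08). Cyp1a1, dim at 4 weeks, was at least 4.65-fold lower than at 2 weeks. Oxidative phosphorylation genes rose in 9 of 40 cases, 10 adjusted over the list alone (camera, adjusted p = 2.46e-07; adjusted p = 0.107 with an estimated correlation). Interferon response genes rose in 8 of 26 cases and fell in 2, or 8 and 4 adjusted over the list alone (camera, adjusted p = 0.00905; adjusted p = 0.11 with an estimated correlation). Among the 2 that fell was Rsad2, an antiviral protein (-0.80 ± 0.07).

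From 2 to 4 weeks 582 genes were higher and 908 lower (39.1% higher), 155 of them by at least 2-fold. With median centring the split was 606 and 587 (50.8% higher). The count of 1490 was 966 without 2-week replicate 2 and 743 in a fit of these 2 groups alone. Of 33 lists 13 passed, 7 also with an estimated correlation: those for sterol synthesis, macrophages, matrix, cell cycle, neutrophils, blood cells and endothelium. With quantile normalization the lists of fatty acid oxidation (7 of 30 higher and 1 lower, 11 and 1 adjusted over the list alone; adjusted p = 0.0072 before and 0.404 after) and amino acid breakdown (5 of 26 higher and 2 lower, 7 and 2 adjusted over the list alone; 0.000256 before and 0.0745 after) lost their calls, as they did with an estimated correlation (adjusted p = 0.264 and 0.225). The cytokine list (7 of 22 lower and 2 higher, 9 and 2 adjusted over the list alone; adjusted p = 0.0396) lost its call with an estimated correlation (adjusted p = 0.11), quantile normalization (0.0596), no filter (0.0673), or without 2-week replicate 3 (0.067), 4-week replicate 2 (0.0645) or 6-week replicate 3 (0.0507). Drug-metabolising enzymes (7 of 28 higher and 6 lower, 8 and 7 adjusted over the list alone, median 0.09 but mean -0.05; adjusted p = 0.0396) lost theirs with an estimated correlation (adjusted p = 0.606), quantile normalization (0.513), or without 0h replicate 1 (0.0531), 2-week replicate 3 (0.0896), 4-week replicate 1 (0.126), 4-week replicate 2 (0.0781) or 6-week replicate 3 (0.0507).

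From 4 to 6 weeks, the last step of the model, the lists of histocompatibility, cytokine, macrophage, lymphocyte and neutrophil genes rose, while the interferon response list (9 of 26 higher and 9 lower, 9 and 11 adjusted over the list alone, median -0.07 but mean 0.15, test direction up) did not pass (camera, adjusted p = 0.708). The class II genes RT1-Bb and RT1-Da rose 9.69-fold (3.28 ± 0.06, adjusted p = 2.23e-09, n = 3 arrays per group) and 6.04-fold (2.59 ± 0.05), and 7 of 14 histocompatibility genes rose and 2 fell, or 8 and 2 adjusted over the list alone (camera, adjusted p = 6.12e-06). RT1-Ba rose 10.8-fold, with 1 of its 3 other probe sets moving the opposite way. Differences between animals, for which the histocompatibility list was written, were not told apart from feeding here either. Cytokine genes rose in 7 of 22 cases, 8 adjusted over the list alone (camera, adjusted p = 3.7e-06): Cxcl1 4.50-fold (2.17 ± 0.09), Cxcl9 4.49-fold (2.17 ± 0.14) and Ccl5 2.71-fold (1.44 ± 0.10). The interleukin Il1b rose 1.81-fold (0.85 ± 0.07). Macrophage markers rose in 12 of 21 cases and fell in 2, or 13 and 2 adjusted over the list alone (camera, adjusted p = 6.93e-07), with Lgals3 up 1.76-fold (0.82 ± 0.06) and the adaptor Tyrobp 1.64-fold (0.72 ± 0.08). Lymphocyte markers rose in 8 of 20 cases, 13 adjusted over the list alone (camera, adjusted p = 2.64e-05), including the granzyme Gzmm, up 2.28-fold (1.19 ± 0.14). S100a8 rose 2.18-fold (1.12 ± 0.10), and 3 of 8 neutrophil markers rose, 4 adjusted over the list alone (camera, adjusted p = 0.00284, and 0.0519 with an estimated correlation). Against 0h, however, the cytokine, macrophage, lymphocyte and neutrophil lists did not pass camera at 6 weeks (adjusted p = 0.395, 0.875, 0.395 and 0.754). In that order 4, 5, 5 and 0 genes were higher and 2, 5, 1 and 0 lower. Adjusted over the list alone, 4, 7, 5 and 0 were higher and 2, 5, 1 and 0 lower.

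Cell cycle genes rose from 4 to 6 weeks in 6 of 31 cases, 12 adjusted over the list alone (camera, adjusted p = 2.17e-06), among them Mcm6, part of the replicative helicase (0.74 ± 0.13). Genes of glucose metabolism fell in 8 of 23 cases and rose in 1, or 9 and 1 adjusted over the list alone (camera, adjusted p = 4.22e-06; adjusted p = 0.052 with an estimated correlation). Igfbp1 fell 2.41-fold (-1.27 ± 0.06) and Pck1 1.47-fold (-0.55 ± 0.06). Endoplasmic reticulum stress genes fell in 5 of 25 cases, or 7 with 1 rising adjusted over the list alone (camera, adjusted p = 0.00104; adjusted p = 0.0637 with an estimated correlation), including the transcription factor Xbp1 (-0.35 ± 0.04). Lipoprotein genes fell in 4 of 22 cases and rose in 1, or 11 and 2 adjusted over the list alone (camera, adjusted p = 0.000204; adjusted p = 0.137 with an estimated correlation), among them the hepatic lipase Lipc (-0.32 ± 0.06). Lox fell 8.90-fold (-3.15 ± 0.14), Cish, a suppressor of cytokine signalling, 4.86-fold (-2.28 ± 0.11), and Cyp1a1 was at least 15.4-fold higher. Sqle rose 1.56-fold (0.64 ± 0.12), but the cholesterol synthesis list, with 5 of 25 genes higher and 2 lower, or 5 and 4 adjusted over the list alone, did not pass camera (adjusted p = 0.39), and its median of 0.02 turned to -0.01 with median centring.

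From 4 to 6 weeks 711 genes were higher and 467 lower (60.4% higher), 128 of them by at least 2-fold. With median centring the split was 465 and 393 (54.2% higher). The count of 1178 was 736 without 6-week replicate 2 and 493 in a fit of these 2 groups alone. Of 33 lists 14 passed, 5 also with an estimated correlation: those for macrophages, cell cycle, cytokines, histocompatibility genes and lymphocytes. With quantile normalization 5 lists that had fallen lost their calls: fatty acid oxidation (adjusted p = 0.00403 before and 0.243 after), amino acid breakdown (0.000183 and 0.102), complement and coagulation (0.00104 and 0.538), oxidative phosphorylation (0.0011 and 0.902) and hepatocyte markers (0.0031 and 0.538). In the same order 6 of 30, 7 of 26, 4 of 26, 2 of 40 and 3 of 25 genes fell and 3, 2, 2, 0 and 0 rose, or 8, 8, 6, 2 and 3 against 3, 2, 2, 0 and 2 adjusted over the list alone. The medians of the last pair turned from -0.06 to 0.02 and from -0.13 to 0.01, and these 5 also lost their calls with an estimated correlation, at adjusted p = 0.306, 0.284, 0.346, 0.306 and 0.52 in that order.

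**Figure D4:**
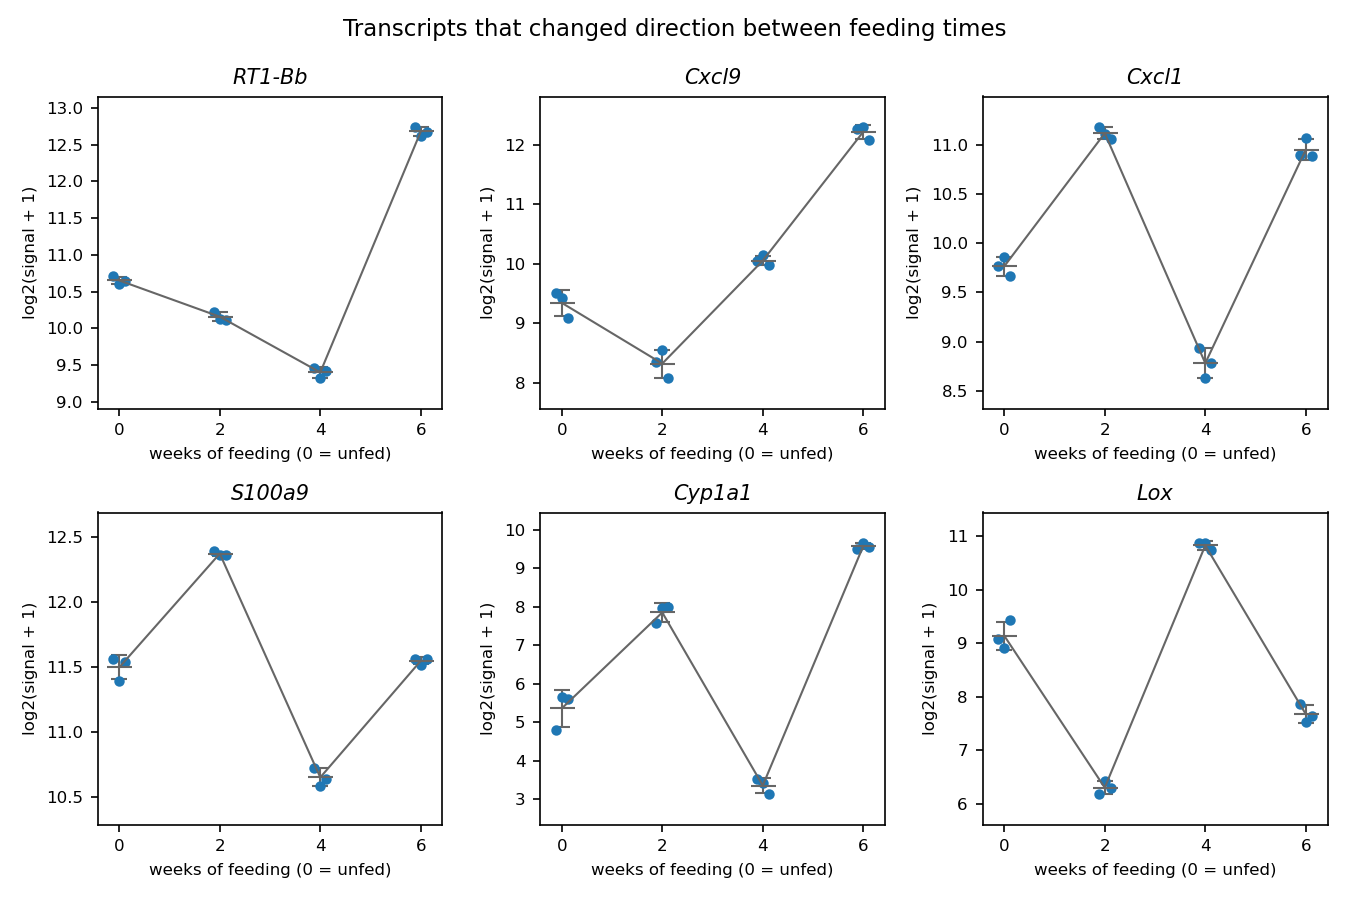
Log2(signal + 1) of 6 transcripts against weeks of feeding (0 = unfed); points are arrays, lines join group means and bars are the SD of 3 arrays. Cxcl1, S100a9 and Cyp1a1 dropped between 2 and 4 weeks and RT1-Bb rose between 4 and 6 weeks, while Lox peaked at 4 weeks.

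Over the 4 groups, 4373 of 11328 genes (38.6%) passed the moderated F test against 0h. At all 3 feeding times 882 genes were higher and 672 lower, among the latter Sqle, Idi1, Tm7sf2, Cyp7a1 and Cyp8b1. In a fit of the fed groups alone, without the 0h arrays that stood apart in sex-biased and clock transcripts and Cpa1, 1728 genes differed between feeding times. Another 160 genes were called in opposite directions at 2 of the feeding times, among them Lox, Cxcl1 and RT1-Bb.

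The 3 comparisons against 0h share their control arrays, so their log2 changes correlate across genes even without any effect. Observed correlations were 0.69 (2 and 4 weeks), 0.71 (2 and 6 weeks) and 0.72 (4 and 6 weeks), where simulated unchanged groups gave 0.50, 0.50 and 0.50. The covariances were 0.182, 0.179 and 0.188, against simulated values of 0.0327, 0.0323 and 0.0327, a difference of 0.149, 0.146 and 0.155. The simulated spread was that between replicates labelled technical, so any difference between the 0h animals and the others would also give an excess. Higher in both members of a pair were 1081, 1124 and 1100 genes, where independent lists of these lengths share 252, 258 and 237. Simulated unchanged groups with shared simulated controls had a mean of 0, 0 and 0 genes called in both. Lower in both were 898, 847 and 934 (215, 179 and 216 for independent lists), and opposite calls numbered 74, 69 and 70. A split of the 3 control arrays would leave a comparison with fewer than 2, so part of the excess may come from the shared controls. Genes are not independent replicates in these correlations.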

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

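The comparisons between feeding times, the gene lists, the second list of male-biased genes and the splits of the arrays were set before their results were seen. The other tests of the female-biased, Cpa1 and clock patterns were chosen only after the result was seen.

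Female-biased transcripts were higher at 0h: 8 of 8 fell in the fed groups, by a median of -2.64 over the 3 times (-2.02 at 2 weeks and -2.63 at 6 weeks). Liver RNA of female rats alone in the 0h samples is excluded, since the median change of 6 male-specific transcripts was only 0.71 and Cyp2c11 had a signal of 20718 at 0h. All 6 were lower at 0h, by 0.22 (Cyp3a2) to 1.26 (Obp3), but no value was predicted for them with RNA of both sexes. Whether some of the RNA came from female rats stays open: a second list of male-biased genes had a median change of 0.28, with 7 of 9 members higher in the fed groups, between the values predicted with and without it. The median change of all genes, -0.011, shows no shift common to all genes. The scaling of each array to a common mean holds this value near 0, so it cannot test other signal differences between the groups. Feeding itself might lower these transcripts: from 2 to 6 weeks the median of the changes of the single genes was -0.23. A fall as large as that from 0h to 2 weeks (-2.02) was predicted to speak for feeding, and was not seen. With 0h as the only unfed group, these values cannot tell feeding from a difference between the animals.

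Cpa1 was higher at 0h, by at least 6.80, 6.97 and 6.81 on the log2 scale over 2, 4 and 6 weeks. Values of 9 other pancreatic enzymes, with a median difference of -0.069, argue against pancreatic tissue in the 0h samples. Their mean log2 signals at 0h ran from 1.33 (Prss2) to 5.85 (Pnlip), near or under the background level, against 12.6 for Cpa1. On all arrays 3 of them were dim. Whether their probe sets detect these transcripts was not tested, so such tissue is not excluded. Female liver could also carry more of it, but no group is labelled by sex, so the difference of Cpa1 from the mean of the fed groups, 7.94 with fed signals under the background level counted as measured, cannot tell. No test of feeding as the cause was made.

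Clock genes were shifted between 0h and every fed group. The side of Nr1d1, 4 genes, changed by a median of -2.54 and the side of Bmal1, 5 genes, by 0.40, a difference of 2.94. A different time of day of tissue collection may give such a shift, but the value includes Nr1d1 and Bmal1, which prompted the test, so it cannot tell. Among the other members Nr1d2 (-2.50), Dbp (-2.58), Cry1 (1.42) and Nfil3 (0.40) moved as predicted. Tef (0.036), Npas2 (-0.032) and Clock (-0.74) did not. The difference was 2.71 at 2 weeks, 3.47 at 4 weeks and 2.64 at 6 weeks, so feeding, which would also act at every time, cannot be told apart by the smallest of them, 2.64.

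Regrouping the arrays set the calls of the real groups beside those of other splits. The other splits mixed arrays of the real groups, so real differences entered their spread or their group means. Their counts are therefore not those expected without any difference. In fits of the 6 arrays of a comparison the real groups gave 2629 (2 weeks against 0h), 2434 (4 weeks), 2457 (6 weeks), 743 (4 against 2 weeks) and 493 genes (6 against 4 weeks). The highest counts of the other splits were 0, 1, 1, 1 and 1. Only the real split, 1 of 10, reached the real count each time, and 10 splits cannot give a share under 0.05. The replicates are labelled technical, so such splits cannot measure chance differences between animals. For the F test over 4 groups only the real grouping, 1 of 100, gave 4373 genes, and the highest other count was 2381.

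A difference between feeding times was the reason for the following values, each tested between the 2 times. Changes against 0h differed between 2 and 4 weeks for 1490 genes and between 4 and 6 weeks for 1178. The macrophage list stood above 0h at 2 weeks (median 0.19) and below it at 4 weeks (-0.40), a step of -0.60. Cyp1a1 was dim at 4 weeks and 2 of its arrays at 0h lay under the background level, so its side of 0h at 4 weeks is not known and its steps below count background as signal; they are bounded only as at least 4.65-fold and 15.4-fold. Nudt11 was dim at 2 weeks, with a step of at least 6.14-fold. Named genes called on opposite sides of 0h at 2 and 4 weeks, with the step between the times, were Lox (4.53), Nudt11 (3.78), Cxcl9 (1.73) and Mx2 (1.13) upwards. Downwards they were Cyp1a1 (-4.50), Cxcl1 (-2.34), Egr1 (-2.30), S100a8 (-1.99), S100a9 (-1.72), Insig1 (-1.33), Igfbp1 (-1.29), Pf4 (-1.11), Lgals3 (-0.92), Cd63 (-0.85), C1qa (-0.80), Rsad2 (-0.80), Hmox1 (-0.78) and Lyve1 (-0.77). Between 4 and 6 weeks the upward steps were those of Cyp1a1 (6.23), RT1-Ba (3.43), RT1-Bb (3.28), RT1-Db1 (2.71), RT1-Da (2.59), RT1-N3 (2.32), Cxcl1 (2.17), Ccl5 (1.44), Gzmm (1.19) and Lgals3 (0.82). The downward steps were those of Lox (-3.15), Cish (-2.28), Mx2 (-1.55), Foxa2 (-1.08) and Crot (-0.76).

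Probe sets without a gene symbol lie outside the comparisons of genes and held changes of their own. Of 6352 tested, 1037 changed at 2 weeks against 0h (496 higher and 541 lower), 1064 at 4 weeks (457 and 607) and 919 at 6 weeks (361 and 558). Their largest falls were -6.14, -5.81 and -6.83 on the log2 scale, and their largest rises 3.53, 3.55 and 3.82.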

How the results depend on the processing

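Of the tests under alternatives, the authors' ratios, the fit of the fed groups alone and the counts without 4 control lists were chosen only after the result was seen. Among values for named genes 8432 kept their side of the threshold, 330 were weaker, 20 stronger and 2 reversed; among values for lists these numbers were 2784, 83, 99 and 4. Leaving out 1 array accounted for 250 of the weaker named values. Signal over background limits the dim genes, whose changes are known only from below, and removing the filter weakened 16 named values.

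Counts moved most with stricter or looser rules, by construction: in the order 2, 4 and 6 weeks against 0h, 4 against 2 weeks and 6 against 4 weeks, 314, 380, 325, 155 and 128 genes changed at least 2-fold (580 in the F test), and 195, 218, 215, 79 and 72 passed treat against 1.5-fold. The authors' ratios reached 2-fold in all 9 pairs for 150, 156 and 165 genes at 2, 4 and 6 weeks. For 4 against 2 and 6 against 4 weeks, the fit of 2 groups alone gave 743 and 493 genes, and unadjusted p-values 2998 and 2719. The fed groups alone gave 1728 genes in the F test, and without the genes of 4 control lists the 5 counts were 3145, 3292, 3042, 1469 and 1158. Lists past the test numbered 3, 3, 4, 7 and 5 with an estimated correlation and 24, 22, 23, 24 and 25 with fry, which asks another question.

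Leaving out each array in turn gave 2474 to 3178, 2654 to 3297, 2427 to 3121, 966 to 1408 and 736 to 1105 genes, 3612 to 4254 in the F test, and 14 to 15, 8 to 12, 9 to 12, 11 to 17 and 14 to 14 lists, with fewer arrays in each fit. Correlations between comparisons that share controls (2 and 4, 2 and 6, 4 and 6 weeks) were 0.646, 0.649 and 0.662 without the filter, and 0.710 to 0.712, 0.728 to 0.732 and 0.735 to 0.737 with 1 control array fewer.

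Reversed were the complement and coagulation list at 4 weeks with quantile normalization (median -0.091), which was 0.032 before, and 3 lists that fry called lower although their medians were above 0: the antioxidant list at 4 weeks (0.073) and from 2 to 4 weeks (0.057) and the sex-biased list from 2 to 4 weeks (0.0017). With the mean of probe sets Me1 reversed from 2 to 4 weeks (-0.035) and Atp5f1c from 4 to 6 weeks (0.74), as other probe sets entered their means; for the lists the cause was not tested.

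With the replicate number as a block, the counts were 2959, 3107, 2877, 1271 and 949 genes, 4019 in the F test, and 14, 11, 10, 12 and 14 lists, the cytokine list from 2 to 4 weeks losing its call (adjusted p = 0.0503). The 3 correlations, 0.690, 0.709 and 0.716, cannot change with the block, since each number occurs once per group. Deviations of 18 same-numbered pairs correlated at -0.02 to 0.08, 0 of them over 0.1, and those of other pairs at -0.06 to 0.05. Of 12 arrays 7 matched their own number best. No strong pairing by number was seen, but a weak one is not excluded.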

Other observations

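The genes in the following paragraphs were chosen after their values were seen; changes are log2 against 0h at 2, 4 and 6 weeks from the same limma fit, n = 3 arrays per group. Abcg5, part of the transporter that secretes cholesterol into bile (-1.31, -3.46 and -2.56), fell at all 3 times, and so did the phospholipid exporter Abcb4 (-0.93, -0.90 and -1.22) and the bile salt pump Abcb11 (-0.62, -0.32 and -0.49). Nr0b2, a repressor of bile acid synthesis, rose at 2 weeks (0.94), fell at 4 (-1.18) and rose at 6 (0.78). The bile acid list, with 8 of 26 genes higher and 8 lower at 2 weeks, 6 and 7 at 4 weeks and 9 and 10 at 6 weeks, did not pass camera (adjusted p = 0.998, 0.744 and 0.395). The elongase Elovl6 (-1.09, -1.94 and -2.34), the desaturases Fads1 (-0.36, -0.93 and -0.69) and Fads2 (-0.56, -0.99 and -0.68), and Acss2, which activates acetate (-0.46, -1.08 and -1.24), fell at all times, while the lipid droplet protein Cideb rose (0.87, 0.69 and 0.88). The fatty acid synthesis list, with 5 of 19 genes higher and 8 lower at 4 weeks and 5 and 10 at 6 weeks, did not pass camera (adjusted p = 0.185 and 0.145). At 4 weeks it passed with quantile normalization (0.0422).

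The metallothioneins Mt1 (-1.35, -2.47 and -1.60) and Mt2A (-2.15, -3.09 and -2.12), which bind zinc, fell at all times. Gclc, which limits glutathione synthesis (1.36, 1.08 and 1.34), the mitochondrial superoxide dismutase Sod2 (0.70, 0.67 and 0.88) and the cell cycle inhibitor Cdkn1a (2.16, 2.12 and 1.55) rose. Lcn2, a siderophore-binding protein of inflamed liver, fell at 4 weeks (-2.49) and did not pass at 2 weeks (0.30) or 6 weeks (-0.30). The iron hormone Hamp fell at 2 weeks (-1.44) and at 4 weeks (-0.61). At 6 weeks the interferon-induced genes Igtp (1.57), Gbp2 (1.09), Psmb9 (1.04) and Irf1 (0.85) rose, while the antiviral genes Mx1 (-0.64), Irf7 (-0.63), Rsad2 (-0.75) and Oasl (-0.54) fell. Their list, with 12 of 26 genes higher and 7 lower at 6 weeks, did not pass camera (adjusted p = 0.0604), but passed with no filter (0.0381) and without 0h replicate 1 (0.0382).

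The authors' deposited log2 ratios, compared with the log2 changes here, gave correlations of 0.941, 0.945 and 0.942 over genes at 2, 4 and 6 weeks.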
